A study of Gallus gallus with 6 samples.

How the data were processed

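RNA was measured in breast tissue of 2 chicken breeds, with 3 libraries of White Leghorn and 3 of Lueyang Silky Fowl. Per the labels' protocols, total RNA was extracted from tissue with a column kit and mRNA libraries were made with a directional (strand-marking) kit. Per the submitters' processing notes, fastp 0.23.2, a read trimming and quality filtering tool, was used. The aligner, the quantification tool, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table of FPKM (fragment counts divided by the length of the gene model and by the number of mapped fragments) with 24356 genes and 1 column per library; the unit is taken from the table's name, and the values, decimals that sum to different totals per library, do not contradict it. Each column was matched to its sample by the sample's title, and the breed was taken from the labels. Nothing in the labels says whether the libraries of a breed came from separate birds, so the p-values measure the spread between these libraries, which may be technical.

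All 24356 genes carry Ensembl chicken identifiers, and the table gives no symbols. The RefSeq gene table used as a reference holds 25635 genes but gives no Ensembl identifiers for them, so 0 of these identifiers could be matched. Genes are therefore reported by identifier, and no chromosome, position, function or sex-linked marker was assigned. The 35 lists of pathway and cell type genes fixed before the data were examined (1275 members) could not be tested for the same reason. The rule for named genes, also fixed before the data were examined, took the largest positive and negative log2 fold changes among genes with an adjusted p under 0.05, a mean FPKM of at least 2 in the higher breed and no overlap between the breeds. The rule also asked for a gene symbol. That part could not be applied, and 2 identifiers are printed per direction.

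Sequencing depth is unknown, since FPKM holds no counts. A search for steps worth 1 read found none. Among 2271 genes under an FPKM of 0.3 in both of the first 2 White Leghorn libraries, the most frequent ratio between the libraries, rounded to 0.01, was shared by only 25 genes. No counting interval or detection floor is given, and a value of 0 is described only as listed at 0. The deposited FPKM summed to between 512965 and 553591 per library. No pair of libraries held identical values.

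For the comparison of breeds, each library's deposited FPKM was divided by 1 scaling factor, the median ratio to the geometric mean over genes at an FPKM of at least 1 in every library. The factors ran from 0.869 to 1.15. Genes were tested where the deposited FPKM was at least 1 in at least 3 of the 6 libraries, which left 9763 genes. The test was limma-trend in limma 3.58.1 (R 4.3.3) on log2(scaled FPKM + 1) with breed as the only term. The p-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. Fold changes are Lueyang Silky Fowl against White Leghorn on this log2(value + 1) scale, which understates the change of genes with low values. Measures of a whole library were compared by two-sided exact permutation tests, which cannot give a p below 0.1 with 3 against 3. Further calculations used Python 3.11.15 with pandas, numpy and scipy.

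The fit was tested on simulated data for the same comparison, with 9763 genes, the spread of the real libraries and 200 changed genes, 50 per fold size. It recovered 20% of the genes changed 1.25-fold, 60% of those changed 1.5-fold, 80% of those changed 2-fold and 100% of those changed 4-fold. Of 136 calls, 6 (4.41%) fell on unchanged genes. The simulation changed few genes, equally in both directions, with independent noise per gene. In the real data 70.6% of the tested genes were called, and the split of calls depended on the scaling. The simulated rates therefore do not describe the real comparison.

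The alternatives fixed before the data were examined were FPKM as deposited, quantile normalization, pseudocounts of 0.1 and 0.01, no filter, a filter at an FPKM of 5, a block for the replicate number, eBayes without the trend or with robust estimation, array weights, and leaving out each library in turn on the same genes. Both breeds carry the replicate numbers 1 to 3. The labels do not say that a number marks a shared bird, batch or day.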

Results

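Breast muscle RNA was compared between the White Leghorn, an egg-laying chicken breed, and the Lueyang Silky Fowl, an indigenous breed. The study asked which genes differ between the breeds in connection with immune and metabolic adaptation. The data were 3 libraries per breed, each with an FPKM value for 24356 genes. The libraries held between 8782 and 9951 genes at an FPKM of at least 1, and 7351 genes were listed at 0 in all 6 libraries. The breeds separated on the first principal component of log2(scaled FPKM + 1), which held 89.5% of the variance. Pearson's r across genes lay between 0.988 and 0.994 for pairs of White Leghorn libraries, between 0.995 and 0.997 for pairs of Lueyang Silky Fowl libraries, and between 0.926 and 0.932 for pairs of different breeds. Genes are not independent replicates, so these values only describe the libraries.

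The expressed transcriptome differed between the libraries of the breeds at most genes. The labels give no batch and do not say whether the libraries of a breed came from separate birds. Anything else that the libraries of a breed share cannot be told apart from breed. In Lueyang Silky Fowl, 3098 of the 9763 tested genes were higher and 3791 were lower than in White Leghorn, which is 70.6% of the genes tested (limma-trend, adjusted p under 0.05, n = 3 per breed). Most differences were small on the log2(scaled FPKM + 1) scale, which understates the change of genes with low values. The median absolute log2 fold change of the called genes was 0.56, and 52.8% of them changed by less than 1.5-fold. At least 2-fold differences were called for 547 higher and 679 lower genes, against 318 and 1217 with FPKM as deposited, 722 and 1181 with a pseudocount of 0.1, and 741 and 1275 with 0.01. The scaled values with a pseudocount of 1 gave at least 4-fold differences for 70 higher and 107 lower genes. The scaled values of the breeds did not overlap at 7271 tested genes (74.5%). For a single gene, chance gives no overlap with a probability of 10%. Genes vary together, so the share over genes can lie far from 10% by chance and is no test. The split of calls depended on the scaling between libraries. The median log2 fold change of all tested genes was -0.06 after scaling by the median of ratios and -0.33 with FPKM as deposited, a shift of -0.27. With FPKM as deposited, 1724 genes were called higher and 5660 lower, so that 23.3% of calls were higher, against 45.0% in the scaled values. After quantile normalization 49.8% of calls were higher, with 3324 higher and 3352 lower genes.

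The gene with the largest increase by the rule fixed beforehand was ENSGALG00000023772. Its FPKM was 6.24 ± 0.757 (SD, n = 3) in White Leghorn and 183 ± 5.36 (SD, n = 3) in Lueyang Silky Fowl, a log2 fold change of 4.98 ± 0.08 (SE, limma adjusted p = 8.63e-09). The next was ENSGALG00000005017, with an FPKM of 2.12 ± 0.419 in White Leghorn and 33.1 ± 1.09 in Lueyang Silky Fowl (SD, n = 3 each) and a log2 fold change of 3.73 ± 0.10 (SE, limma adjusted p = 2.75e-08). The ranking uses the log2(scaled FPKM + 1) scale, which places genes near 0 in a breed lower than their ratio of FPKM would. By this rule, the largest decrease was that of ENSGALG00000011404. Its FPKM went from 88.3 ± 6.51 in White Leghorn to 2.95 ± 0.106 in Lueyang Silky Fowl (SD, n = 3 each). Its log2 fold change was -4.21 ± 0.08 (SE, limma adjusted p = 8.96e-09). ENSGALG00000011740 followed, with an FPKM of 78.4 ± 4.89 in White Leghorn and 2.66 ± 0.514 in Lueyang Silky Fowl (SD, n = 3 each) and a log2 fold change of -4.16 ± 0.10 (SE, limma adjusted p = 1.64e-08). Each of these 4 genes was called in the same direction with any library left out and under each alternative scaling, pseudocount, filter and variance setting. The 12 genes with the largest increases by this rule had log2 fold changes from 2.97 to 4.98, with a median FPKM of 8.29 in White Leghorn and 87.4 in Lueyang Silky Fowl. The 12 with the largest decreases had log2 fold changes from -4.21 to -3.54, with a median FPKM of 38.0 in White Leghorn and 1.76 in Lueyang Silky Fowl. Of these 12, 1 was listed at 0 in all 3 Lueyang Silky Fowl libraries, so its fold change depends on the pseudocount.

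**Figure D1:**
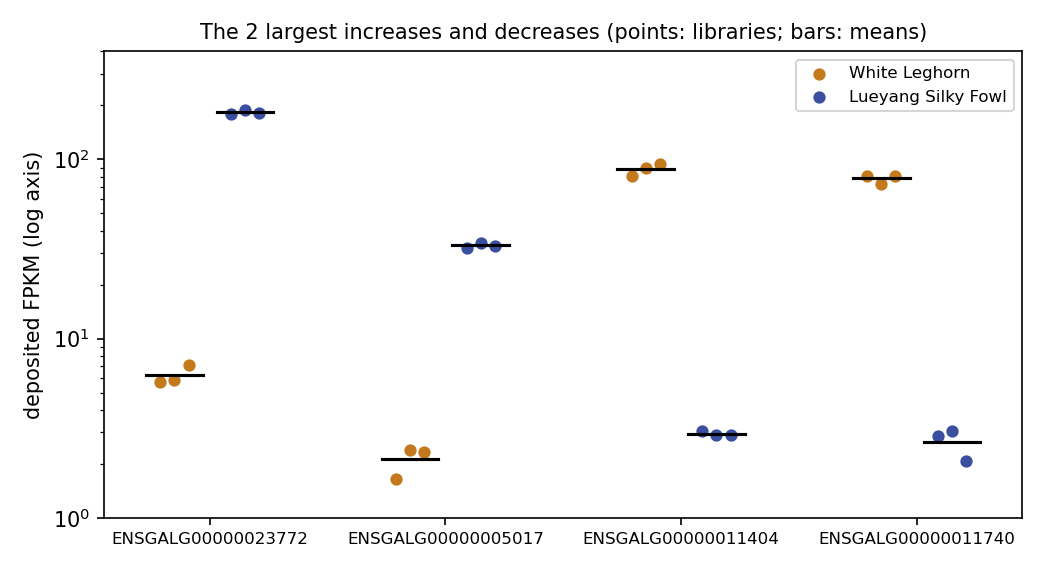
Deposited FPKM (log axis) of the 2 largest increases and the 2 largest decreases among called genes whose breeds did not overlap and whose mean FPKM was at least 2 in the higher breed. Each point is a library and each bar a breed mean. ENSGALG00000023772 and ENSGALG00000005017 were higher in all 3 Lueyang Silky Fowl libraries, and ENSGALG00000011404 and ENSGALG00000011740 in all 3 White Leghorn libraries.

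The most abundant genes took a larger share of the transcriptome in each Lueyang Silky Fowl library than in any White Leghorn library, though 3 libraries against 3 cannot reach an exact p under 0.1. The 10 most abundant genes of each library held 30.3% ± 0.333 of summed FPKM in Lueyang Silky Fowl and 25.4% ± 0.442 in White Leghorn (SD, n = 3 each, two-sided exact permutation p = 0.1). The 100 most abundant held 61.3% ± 0.431 and 54.2% ± 0.871 (SD, n = 3 each, exact permutation p = 0.1). It took 35.3 ± 1.15 genes to reach 50% of summed FPKM in Lueyang Silky Fowl and 69.7 ± 4.93 genes in White Leghorn (SD, n = 3 each, exact permutation p = 0.1). These shares do not change with a scaling factor per library, and the breeds did not overlap in any of them. The single most abundant gene held 5.66% of summed FPKM in Lueyang Silky Fowl and 4.86% in White Leghorn, and its log2 fold change was 0.62 ± 0.09 (SE, limma adjusted p = 0.0004) after scaling and 0.29 (limma adjusted p = 0.0024) with FPKM as deposited. The second most abundant gene held 3.49% in Lueyang Silky Fowl and 4.67% in White Leghorn. After scaling, its log2 fold change was -0.02 ± 0.09 (SE, limma adjusted p = 0.883), and with FPKM as deposited it was lower in Lueyang Silky Fowl by a log2 fold change of -0.35 (limma adjusted p = 0.000672).

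**Figure D2:**
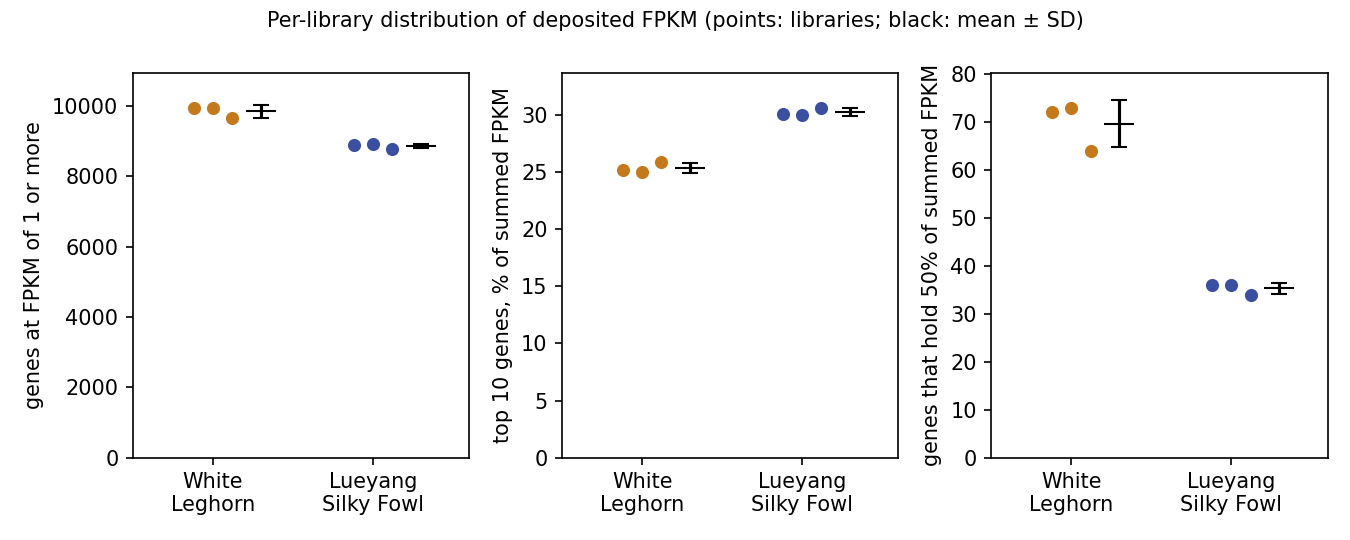
Genes at an FPKM of at least 1, percent of summed FPKM in the 10 most abundant genes, and number of genes that hold 50% of summed FPKM, per library (points, coloured by breed) with the breed mean and SD (black, n = 3). The Lueyang Silky Fowl libraries hold fewer genes at an FPKM of at least 1 than any White Leghorn library, a larger share in the 10 most abundant genes, and fewer genes at 50%.

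Each Lueyang Silky Fowl library had fewer genes at an FPKM of at least 1 than any White Leghorn library. The number of genes at an FPKM of at least 1 was 8858 ± 66.8 in Lueyang Silky Fowl and 9844 ± 173 in White Leghorn (SD, n = 3 each, exact permutation p = 0.1). At a scaled FPKM of at least 1, the numbers were 9083 ± 23.3 and 9638 ± 138 (SD, n = 3 each, exact permutation p = 0.1). The gap depended on the level and the scaling. At an FPKM of at least 10, Lueyang Silky Fowl had 3693 ± 43.8 genes and White Leghorn 4331 ± 103 as deposited, and 3946 ± 4.0 and 4016 ± 28.6 after scaling (SD, n = 3 each). At an FPKM of at least 100 the direction turned with the scaling, with 542 ± 15.3 genes in Lueyang Silky Fowl and 591 ± 16.8 in White Leghorn as deposited, and 624 ± 7.02 and 515 ± 29.3 after scaling (SD, n = 3 each). The direction of the called genes followed their abundance, taken as the mean scaled FPKM over all 6 libraries. Of 60 genes at 1000 or more, 47 were higher and 1 was lower in Lueyang Silky Fowl, with 33 higher and 14 lower in FPKM as deposited, while quantile normalization turned the balance to 24 higher and 28 lower. Of 504 genes from 100 to 1000, 281 were higher and 118 lower, while the balance turned to 172 higher and 233 lower in FPKM as deposited and to 200 higher and 210 lower after quantile normalization. Of 3471 genes from 10 to 100, 1542 were higher and 1119 lower, against 868 higher and 1840 lower in FPKM as deposited, where the balance turned, and 1348 higher and 1307 lower after quantile normalization. Of 5418 genes from 1 to 10, 1202 were higher and 2308 lower, against 630 and 3311 in FPKM as deposited, while quantile normalization turned the balance to 1710 higher and 1701 lower. The 310 tested genes under 1 are left out here, because the filter lets such a gene in mostly through the breed where it is high. Of these 310 genes, 26 were called higher and 245 lower, and the counts over all 9763 tested genes include them. Quantile normalization gives every library the same distribution, so it removes a trend with abundance by construction. Across the 9422 tested genes with a mean of at least 1 and a value above 0 in every library, Spearman's rho between abundance and log2 ratio was 0.27; genes are not independent replicates.

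**Figure D3:**
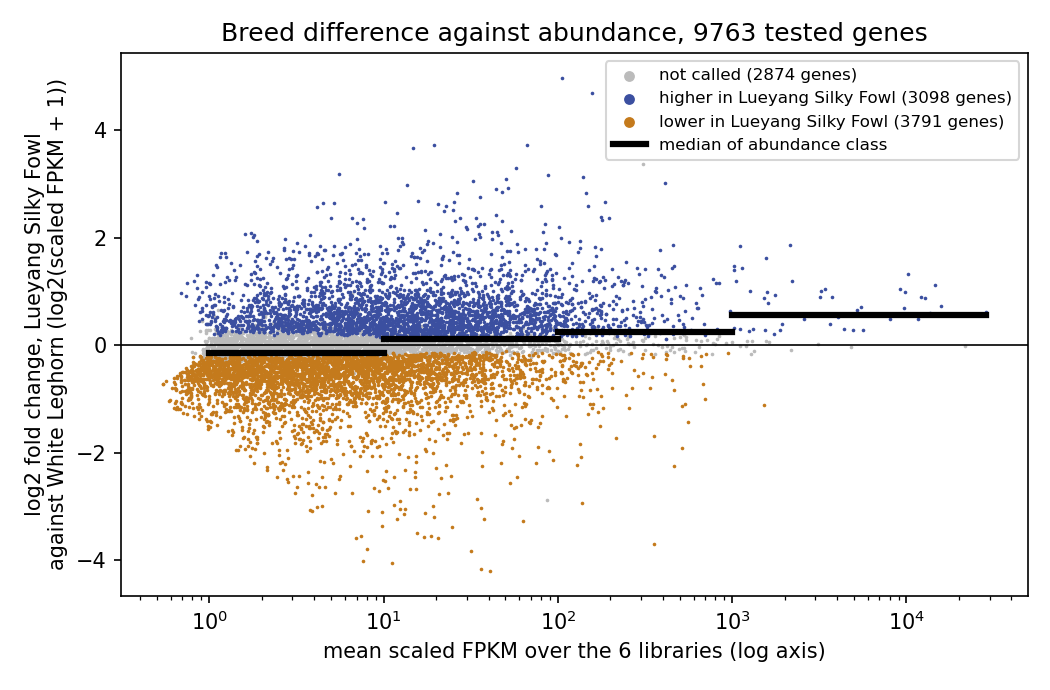
Log2 fold change of Lueyang Silky Fowl against White Leghorn on the log2(scaled FPKM + 1) scale against the mean scaled FPKM over the 6 libraries (log axis), for the 9763 tested genes. Points are coloured by call, and black lines give the median of each abundance class, which runs from -0.15 at 1 to 10 to 0.56 at 1000 or more. Genes under 1 have no line, since the filter selects them.

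A small group of genes was listed in one breed and near 0 in the other. At a deposited FPKM of at least 1 in all 3 libraries of a breed and under 0.1 in all 3 of the other, 29 genes were seen in White Leghorn and near 0 in Lueyang Silky Fowl, and 3 genes the other way. On scaled FPKM the counts were 25 and 6. The median FPKM in the breed that had them was 2.17 for the 29 genes and 2.84 for the 3 genes, and the highest was 17.2. Of the 29 genes, 7 were listed at 0 in all 3 Lueyang Silky Fowl libraries, and of the 3 genes, 1 was listed at 0 in all 3 White Leghorn libraries. The other 9 ways to split the 6 libraries into 3 and 3 gave at most 1 such gene on a side. Each of these splits puts libraries of both breeds on each side, so a gene that separates the breeds cannot qualify. Leaving out White Leghorn replicate 3 raised the 3 genes to 7, leaving out replicate 2 raised them to 6, and leaving out replicate 1 raised them to 5. The 29 genes became 30 to 36 without a library. The rule asks for every library, so leaving a library out can only keep or raise a count.

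The libraries of a breed differed little. At the 564 genes with a mean scaled FPKM of at least 100, the median coefficient of variation was 2.27% in Lueyang Silky Fowl and 7.55% in White Leghorn (n = 3 each). With FPKM as deposited it was 2.55% in Lueyang Silky Fowl and 5.71% in White Leghorn. From 2 libraries each, the scaled value for White Leghorn was 8.23% without replicate 1 and 9.39% without replicate 2. Values from 2 libraries cannot be set against those from 3, and none was computed for Lueyang Silky Fowl. The White Leghorn value rested on replicate 3, without which it was 1.81%. In that library, genes at 1000 or more lay at a median of 0.17 above the other White Leghorn libraries on the log2 scale, and genes from 1 to 10 at -0.06. Without White Leghorn replicate 3, 3296 genes were called higher and 4019 lower in Lueyang Silky Fowl.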

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

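Without a library, the calls ran from 2826 to 3296 genes higher, 3447 to 4019 lower, 524 to 565 at least 2-fold higher and 670 to 703 at least 2-fold lower in Lueyang Silky Fowl, and no called gene changed direction. With FPKM as deposited, 1724 genes were higher and 5660 lower, 318 at least 2-fold higher and 1217 at least 2-fold lower. The construction accounts for the move of the median by -0.27, and 5515 of the 6889 calls kept their direction and threshold while 68 were called in the other direction. After quantile normalization, 3324 genes were higher and 3352 lower, with 572 and 567 at least 2-fold; 5828 calls were kept and 21 were called in the other direction. The genes at least 2-fold lower rose to 1181 with a pseudocount of 0.1 and to 1275 with 0.01, which shrink low genes less. With only the 6184 genes at an FPKM of at least 5, 2475 were higher and 2235 lower, with 453 and 445 at least 2-fold, since fewer low genes were tested, and the balance turned to 52.5% higher. Genes in Lueyang Silky Fowl and near 0 in White Leghorn numbered 6 on scaled FPKM, 1 when listed at 0 was required, 0 at an FPKM of at least 5, and 3 to 7 without a library. Genes in White Leghorn and near 0 in Lueyang Silky Fowl numbered 25 on scaled FPKM, 7 when listed at 0 was required, 5 at an FPKM of at least 5, and 30 to 36 without a library. These settings for genes near 0 were chosen after seeing the data. Leaving out a library can only keep or raise these counts of genes near 0. With the replicate number as a block, 3169 genes were higher and 3820 lower, with 547 and 679 at least 2-fold. Deviations from the breed mean correlated across genes at r = -0.22, -0.03 and 0.05 for same-numbered libraries. For differently numbered libraries, r ran from -0.25 to 0.26. Deviations from a mean of 3 libraries depend on each other, so these values cannot exclude a shared batch or day. The labels do not pair the numbers, and they are not read as pairs. The 4 named genes kept direction and call in all 16 alternatives, with log2 fold changes of 4.67 to 5.21 for ENSGALG00000023772, 3.46 to 4.31 for ENSGALG00000005017, -4.56 to -4.14 for ENSGALG00000011404 and -4.56 to -4.04 for ENSGALG00000011740. Their highest adjusted p was 3.06e-06. The tests of gene lists, and the alternatives fixed for them, were not run, since no list member could be matched to an identifier. Depth is unknown, so what it limits could not be set.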

Other observations

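The tests of RNA quality or preparation, of sex within a breed and of shared variable genes were chosen after values had been seen, as were the counts of genes at an FPKM of at least 1 on scaled values and of genes near 0.

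One pattern to follow up is the lower number of genes at an FPKM of at least 1 in Lueyang Silky Fowl (8858 against 9844 in White Leghorn). A larger share of the most abundant genes would lower the FPKM of all others by 1 factor, but after scaling the difference was still -555 genes, against a range of at most 241 genes within a breed. A single factor per library therefore accounts for only part of the gap at an FPKM of 1. At 10, scaling took the gap from -639 to -70.3 genes, and at 100 it turned the gap from -48.3 to 109 genes. The scaling centres the median ratio of the genes whatever the cause. What it removes is therefore no evidence for a larger share of the most abundant genes. Lower depth alone would not shift FPKM, but the median breed difference of genes from 1 to 10 minus that of genes from 10 to 100 was -0.31 on the log2 scale (-0.36 to -0.28 with each library left out, and -0.31 with no filter). A difference in RNA quality or library preparation that follows abundance stays open: White Leghorn replicate 3 departed from its own breed along the same axis by -0.13, the labels give no batch, and any batch that follows breed cannot be told apart from it. A breed difference in the tissue, such as other proportions of cell types, may also hold and was not tested, nor were GC content and gene length.

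A second pattern is the 32 genes listed in one breed and near 0 in the other, 29 of them in White Leghorn, on deposited FPKM. A sequence or copy difference of a breed against the reference, or birds of 1 sex in each breed, could give such genes. Neither can be told apart from a change in expression for these 32 genes, because their sequence and chromosome were not used here. With no filter, 70.3% of the 3544 genes with a mean scaled FPKM of 0.1 to 1 had a lower mean in Lueyang Silky Fowl. Whether the imbalance among the 32 genes goes beyond this broader shift was not tested. One gene had FPKM from 499 to 641 in 3 libraries and was listed at 0 in the other 3, of which 2 were White Leghorn and 1 was Lueyang Silky Fowl.

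Within a breed, 5 genes in White Leghorn and 4 in Lueyang Silky Fowl were at 5 or more in 1 library and under 0.1 in another. Birds of different sex within a breed could give a set of genes that are off in the same libraries. At most 2 of these genes shared their libraries in a breed, and since the number of W chromosome genes among the identifiers is not known, this leaves the sex of the birds open.

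In a further pattern, the most variable genes of the breeds overlapped more than shuffled lists did, although most were not shared. Among 4035 genes with a mean scaled FPKM of at least 10, ranked by spread within 20 abundance bins, 95 of the 420 in the top 10% of each breed were shared, where shuffling gave 43.8 on average and at most 69 (permutation test with 10000 shuffles, p = 0.0001, the smallest they can give). The shuffling treats genes as independent, which genes that vary together over 3 libraries are not, so this p is too small. Without White Leghorn replicate 3 the overlap was 100 genes. What the shared genes have in common was not tested. Features of a gene that make its estimate noisy, such as length or shared sequence, stay open too.

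Each of the 4 counts of calls was reached by 1 of the 10 splits of the 6 libraries, the real one. The highest other split gave 1 gene, against 3098 higher, 3791 lower, 547 at least 2-fold higher and 679 at least 2-fold lower in the real one. With 10 splits no share under 0.05 can be reached. The other splits mix the breeds, so breed differences widen the spread within each side. Their low counts therefore do not show what chance gives.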
